A study of Mus musculus with 10 samples.

How the data were processed

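The series holds 10 samples of sorted growth plate-like chondrocytes, with 12 replicate tables, 3 for each of the primary and secondary screen at day 4 and day 15. Replicates 1 and 2 of the secondary screen share a sample at each day, with a table for each. The authors deposited, for every gene in every replicate, the log fold change between the top and bottom 10% of cells by CD200, averaged over the gene's guides, with the values of the single guides to 2 decimals. The unit was read as log2, since the deposited tables name a log fold change without its base, and no value was converted to a fold. The deposited tables also hold a p-value per gene as −log10, and the base 10 was found from entries with 1 guide. Means of the 3 replicates, which the authors also deposited, were used only as a check. For the primary screen all 22347 averaged values lay within 0.001 of the mean of the replicate values. For the secondary screen the averaged tables hold fewer guides, and 136 of 209 at day 4 and 130 of 209 at day 15 did. The genome build is GRCm38 per the submitters' processing notes. How reads were counted and normalized, and any pseudocount, is not stated per the labels and the file headers. The barcode files, which name the library conditions, were not used here.

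The depth is unknown, because no read counts are given, so no interval or limit that needs it is reported. The direction was taken from Cd200, on the premise that its guides are depleted from CD200-high cells. Genes with fewer than 3 guides and control guides were left out of the tests. This left 20710 genes in the primary and 238 in the secondary screen. Each replicate of the primary screen was centred on its median over genes. Each replicate of the secondary screen was centred on the median of its control guides, since its genes were chosen on the primary screen. For each screen and day, limma 3.58.1 in R 4.3.3 tested the mean of the 3 replicates against 0 (lmFit with an intercept, eBayes, two-sided). The difference between days was tested with limma in a fit of the 6 replicates of a screen without a block. P-values were adjusted by Benjamini-Hochberg over all genes of a test, with a threshold of 0.05.

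Gene lists, 31 in number, were tested in the primary screen by camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, for each day and for the difference. Camera with an estimated correlation, which rests on 2 residual degrees of freedom at 1 day and 4 for the difference, was an alternative. Lists, tests and the rule for named genes were fixed before the data were examined. The rule takes Cd200, the 10 highest and 10 lowest means per screen and day among genes past the threshold with the same sign in 3 replicates and in at least 75% of guides, the 5 highest and lowest per difference, and up to 4 members of each list past the threshold. Of the 10 lowest at secondary day 4, 3 are not reported here. Overlaps between screens were set beside those of independent lists, and same-sign shares were given exact Clopper-Pearson 95% intervals.

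A second test compared each gene's mean over guides and replicates with 100000 random sets of as many guides, drawn from all guides or from control guides. The latter, fits with only guides listed under 1 gene, and fits with only the secondary guides absent from the primary library were alternatives chosen after seeing the data. Other alternatives were the median over guides, scaling of each replicate, no minimum of guides, robust eBayes, other centring, both days in one fit, the deposited p per gene, a replicate block, weights per day, a rank test of the lists, replicates 1 and 2 of the secondary screen averaged into 1, and each replicate left out in turn.

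The tests were tried on simulated data that lack parts of the real spread. For limma and camera, values were independent normal draws with the spread between replicates. No guide effect was repeated across replicates, no guide was shared and genes were drawn independently. The false calls below are thus those of that setting and can be more frequent in the real data. For the test across guides, the spread was that of control guides. Of 200 genes per size shifted by 0.5, 1 and 2 (log2), limma recovered 79.5%, 100% and 100% at primary day 4, with 3.12% of calls false, and 1%, 13% and 92% at primary day 15, with 4.07% of calls false. For the primary difference it recovered 0.5%, 4.5% and 56%, with 0.813% of calls false. Of 20 genes per size it recovered 35%, 80% and 85% at secondary day 4, 5%, 55% and 95% at secondary day 15 (no false calls in either), and 15%, 60% and 80% for the secondary difference, with 6.06% of calls false. A test across guides against random sets of all guides recovered 77%, 100% and 100% at primary day 4 and 0%, 1.5% and 37.5% at primary day 15. In a simulation of primary day 4 with the ribosome list shifted by 0.3, camera called that list and no other. Gene coordinates are those of RefSeq genes on GRCm38, matched by symbol. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.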

Results

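Pooled CRISPR knockout screens were made in growth plate-like chondrocytes (GPLC), a mouse cell line, which carried Cas9 and a library of guides. The cells were grown for 4 or 15 days and sorted on CD200, a membrane protein that the series describes as a marker of chondrocyte maturation. The barcode of each guide was sequenced from genomic DNA of the top 10% and the bottom 10% of cells. Each deposited value is the log fold change of a gene's guides between these fractions, so a positive value means that the guides were more abundant in CD200-high cells. A primary, genome-wide screen and a smaller secondary screen each had 3 replicates at day 4 and 3 at day 15, 12 replicates in all. The primary library held 79633 different guides and 20710 genes with at least 3 guides (median 4 guides per gene). The secondary library held 2300 guides, of which 645 were also in the primary library, and 238 genes with at least 3 guides (median 10). The tables give no read counts, so the depth behind each value is unknown. The log base is not stated and was taken as 2. Values below are centred log2 means over 3 replicates ± SD (n = 3), and each adjusted p is that of limma unless named otherwise. These p-values measure the spread between replicates of a screen. The sample titles call the replicates biological, without saying whether they share transduced cells. Replicates 1 and 2 of the secondary screen are held by 1 sample at each day.

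Cd200 itself, the sorted marker (gene ID 17470, chromosome 16, 45382111 to 45409060, GRCm38), had negative values in all 12 replicates. In the primary screen it lay at -2.30 ± 0.28 at day 4 (adjusted p = 7.12e-10) and -1.73 ± 0.39 at day 15 (adjusted p = 0.00615). In the secondary screen it lay at -1.47 ± 0.73 at day 4 (adjusted p = 0.0367) and -2.37 ± 0.54 at day 15 (adjusted p = 0.00499). The direction of the values was taken from Cd200, on the premise that its loss places cells in the CD200-low fraction. Only the shared sign across the 12 replicates is therefore a result. Across guides, Cd200 stood apart from random sets of control guides at primary day 4 (adjusted p = 0.000583) but not at primary day 15 (adjusted p = 0.597). At secondary day 4 replicate 2 gave -0.63 against -1.85 and -1.93 in the others.

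The first comparison asked which knockouts moved cells between the CD200 fractions at day 4 in the primary screen. The highest value was that of Sufu, a repressor of Hedgehog signalling (chromosome 19, 46396896 to 46488804), at 3.67 ± 0.24 (adjusted p = 3.71e-13). Next were Eed (2.69 ± 0.10) and Ezh2 (1.91 ± 0.31), which with Suz12 (1.56 ± 0.01) encode the core of Polycomb repressive complex 2. Between Ezh2 and Suz12 lay the histone methyltransferase gene Dot1l (1.90 ± 0.31) and Ptch1, the receptor that restrains Hedgehog signalling (1.85 ± 0.18). The rest of the 10 highest were Strap at 1.40 ± 0.14, the splicing regulator Ptbp1 at 1.24 ± 0.48, the SUMO ligase gene Pias1 at 1.18 ± 0.19 and Aldh2 at 1.15 ± 0.54. After Cd200, the lowest values were those of Brd2, a bromodomain reader of acetylated histones (-1.25 ± 0.10), the calcium pump gene Atp2b1 (-1.13 ± 0.26), the ribosomal gene Rps28 (-1.13 ± 0.26) and Ccm2 (-1.12 ± 0.27). Cop1, which encodes a ubiquitin ligase, lay at -1.08 ± 0.26, Ywhae at -1.06 ± 0.17, the retromer subunit gene Vps29 at -1.05 ± 0.16, the nuclear import gene Kpnb1 at -1.02 ± 0.06 and the histone demethylase gene Kdm1a at -1.01 ± 0.33.

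**Figure D1:**
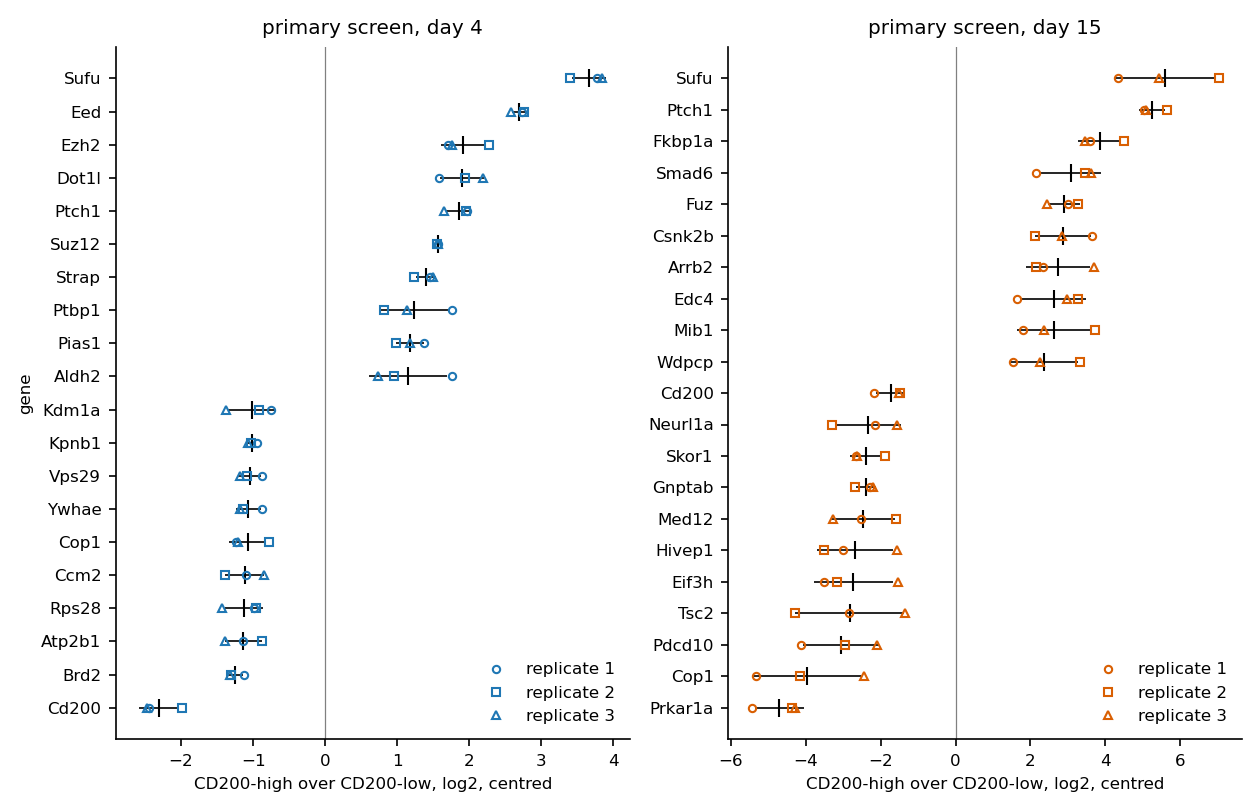
Centred log2 values of Cd200 and of the 10 highest and 10 lowest genes named by rule in the primary screen at each day. Open symbols are the 3 replicates, the tick is their mean and the line 1 SD, and Sufu is at the top at both days.

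Of the 31 gene lists tested, 3 were higher than other genes at day 4. In the Polycomb list 10 of 24 measured members were higher and 1 was lower (adjusted over the list alone, 11 and 3), with a mean of 0.43 (camera adjusted p = 6.58e-08), Mtf2 among them at 0.83 ± 0.12. In the list of the primary cilium and intraflagellar transport, on which Hedgehog signalling depends, 13 of 36 members were higher and 0 lower (adjusted over the list alone, 17 and 0), with a mean of 0.26 (camera adjusted p = 5.01e-09). Its leading members were Kif3b (0.72 ± 0.20), Ift81 (0.58 ± 0.15), Mks1 (0.56 ± 0.33) and B9d1 (0.53 ± 0.20). Across guides 3 members of this list stood apart from random sets of control guides, and B9d1 was not among them. Those control guides lay 0.10 above the median of genes, which makes a higher call harder to reach. In the PTHrP-Ihh-PKA list, signals that set the pace of growth plate maturation, 5 of 22 members were higher and 1 lower (adjusted over the list alone, 5 and 1), with a mean of 0.35 and a median of 0.11 (camera adjusted p = 0.000333). Sufu and Ptch1 are members, and the SD over members was 0.90. Gnas, the stimulatory G protein, lay at 1.03 ± 0.02 and Prkar1a, the subunit that restrains protein kinase A, at -1.01 ± 0.02. With an estimated correlation in place of the preset one, these calls were lost, with adjusted p = 0.163 for Polycomb, adjusted p = 0.163 for the cilium and adjusted p = 0.217 for PTHrP-Ihh-PKA with an estimated correlation.

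A further 10 lists were lower at day 4. Knockouts of the cytosolic ribosome were lower in 40 of 45 members (42 adjusted over the list alone, none higher in either count), with a mean of -0.58 (camera adjusted p = 1.37e-32). Examples were Rps2 (-0.90 ± 0.49), Rps3 (-0.89 ± 0.22), Rps7 (-0.88 ± 0.16) and Rps4x (-0.83 ± 0.20). The proteasome was lower in 23 of 32 members (29 adjusted over the list alone), with a mean of -0.51 (camera adjusted p = 4.86e-21) and Psmc4 at -1.01 ± 0.20, Psmd14 at -0.94 ± 0.27, Psma6 at -0.79 ± 0.36 and Psma4 at -0.69 ± 0.28. With an estimated correlation these became adjusted p = 0.124 for both lists. ER-Golgi trafficking was lower in 13 of 43 members and higher in 0 (adjusted over the list alone, 18 and 1; mean -0.22, camera adjusted p = 7.77e-06), with Copa (-0.83 ± 0.12), Tmed2 (-0.62 ± 0.28), Sec13 (-0.62 ± 0.28) and Arcn1 (-0.60 ± 0.09). Endosome, retromer and lysosome genes were lower in 11 of 33 members and higher in 0 (adjusted over the list alone, 16 and 1; mean -0.25, camera adjusted p = 8.72e-06), with Rab7 (-1.01 ± 0.16), Commd2 (-0.71 ± 0.26) and Atp6ap1 (-0.60 ± 0.11) beside Vps29. For both trafficking lists the adjusted p = 0.163 with an estimated correlation.

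Insulin, IGF and mTORC1 genes were lower in 6 of 36 members and higher in 0 (adjusted over the list alone, 8 and 1), with a mean of -0.15 (camera adjusted p = 0.00931, and adjusted p = 0.248 with an estimated correlation). The members that moved included Tsc2, which restrains mTORC1 (-0.87 ± 0.17), and Rptor and Rraga, which activate it (-0.44 ± 0.12 and -0.45 ± 0.26), with Akt2 at -0.44 ± 0.34. N-glycosylation genes were lower in 7 of 37 members and higher in 1 (adjusted over the list alone, 8 and 1; mean -0.12, camera adjusted p = 0.0216, and adjusted p = 0.397 with an estimated correlation), with Alg5 (-0.50 ± 0.19), Alg11 (-0.43 ± 0.09), Mgat1 (-0.42 ± 0.24) and Alg14 (-0.42 ± 0.12). Cullin ligase and neddylation genes were lower in 10 of 34 members and higher in 1 (adjusted over the list alone, 14 and 2), with a mean of -0.16 (camera adjusted p = 0.0111). Dcaf1 (-0.73 ± 0.08), Keap1 (-0.68 ± 0.28), Nedd8 (-0.56 ± 0.34) and Uba3 (-0.52 ± 0.35) led them. The MLL-COMPASS and SAGA list, of histone modifiers that activate transcription, was lower in 6 of 30 members and higher in 0 (adjusted over the list alone, 8 and 0), with a mean of -0.14 (camera adjusted p = 0.034). Wdr5 (-0.77 ± 0.17), Kmt2b (-0.75 ± 0.18), Kmt2c (-0.64 ± 0.08) and Ash2l (-0.58 ± 0.16) led it. Integrin, focal adhesion and actin genes were lower in 6 of 33 members and higher in 2 (adjusted over the list alone, 8 and 3; mean -0.13, camera adjusted p = 0.034), with Actr2 (-0.74 ± 0.27), Cdc42 (-0.67 ± 0.10), Arpc4 (-0.65 ± 0.01) and Arpc2 (-0.48 ± 0.03). The m6A writer list, for a methyl mark on RNA, also holds genes of readers (Ythdf1, Ythdf2, Ythdf3 and Ythdc1) and erasers (Alkbh5 and Fto) of that mark. Its mean is thus not one of writers alone. It was lower in 4 of 13 members and higher in 0 (adjusted over the list alone, 5 and 1), with a mean of -0.20 (camera adjusted p = 0.0498). Mettl14 lay at -0.91 ± 0.19, Cbll1 at -0.67 ± 0.19, Virma at -0.51 ± 0.23 and Wtap at -0.45 ± 0.08. For the cullin, MLL-COMPASS, integrin and m6A lists the adjusted p = 0.322 with an estimated correlation. By the rank test of the lists, adjusted p = 0.121 for MLL-COMPASS, 0.0507 for integrin and 0.192 for m6A, so these calls were lost there too.

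The other 18 lists were not past the threshold at day 4. Among BMP and TGF-beta genes 4 of 28 were higher and 2 lower (adjusted over the list alone, 5 and 2, camera adjusted p = 0.0934). Of the ER import, folding and quality control genes 2 of 37 were higher and 8 lower (the same counts adjusted over the list alone, camera adjusted p = 0.0847). In mitochondrial respiration 0 of 57 were higher and 6 lower (the same adjusted over the list alone, camera adjusted p = 0.0932). Chondrocyte transcription factors went both ways, with 3 of 23 higher and 4 lower (the same adjusted over the list alone, camera adjusted p = 0.733), a mean of -0.02 and a median of 0.08. FGF and MAPK genes had 2 of 27 higher and 5 lower (adjusted over the list alone, 5 and 6, camera adjusted p = 0.733), and Wnt and beta-catenin genes 3 of 25 higher and 5 lower (adjusted over the list alone, 4 and 6, camera adjusted p = 0.748). Hippo-YAP genes had 3 of 19 higher and 2 lower, Notch genes 1 of 17 higher and 0 lower, and SWI/SNF genes 1 of 23 higher and 0 lower (the same adjusted over the list alone). Their camera adjusted p values were 0.473, 0.733 and 0.327. The hypoxia and VHL list had 1 of 12 higher and 2 lower (adjusted over the list alone, 1 and 3) and the histone deacetylase complexes 2 of 23 higher and 3 lower (adjusted over the list alone, 5 and 8), each with camera adjusted p = 0.209.

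The Mediator and CDK8 list had 2 of 31 members higher and 5 lower at day 4 (adjusted over the list alone, 2 and 6), and the GPI anchor list 0 of 22 higher and 4 lower (the same adjusted over the list alone), each with camera adjusted p = 0.473. Cartilage matrix genes had 1 of 30 higher and 0 lower (adjusted over the list alone, 0 and 0, camera adjusted p = 0.209), and glycosaminoglycan synthesis genes 2 of 31 higher and 2 lower (the same adjusted over the list alone, camera adjusted p = 0.949). Of the cell cycle and p53 genes 1 of 28 was higher and 3 were lower (adjusted over the list alone, 1 and 4, camera adjusted p = 0.743). Genes of Mendelian short or tall stature had 6 of 49 higher and 11 lower (adjusted over the list alone, 8 and 12, camera adjusted p = 0.986), and the sign of the test differed from that of their mean of 0.02. Olfactory and vomeronasal receptor genes, which cartilage is not known to express and which served as a negative control, had 40 of 1450 higher and 106 lower (adjusted over the list alone, 34 and 98, camera adjusted p = 0.473).

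In the test at day 4, 2429 of 20710 genes were past the threshold, 627 higher and 1802 lower. A total of 581 of these had no guide of their own, since every guide was also listed under another gene, and with guides listed under 1 gene alone 1605 genes passed. Among control guides grouped as in the deposited tables, 18 of 250 groups passed, which is 7.2% against 11.7% of genes and 10.1% of the receptor genes. Among genes whose guides were all their own, 1553 of 17302 passed, and 35 of 915 of the receptor genes. Control guides lay 0.10 above the median of genes, and with that as the centre 3402 genes passed, 226 higher and 3176 lower. Across guides 2413 genes stood apart from random sets of control guides, 82 higher and 2331 lower. That test kept the gene centre, so the offset of 0.10 favoured lower over higher calls. Of the control guides, 968 had no site and 12 had 1 intergenic site, so most were not made to cut.

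**Figure D2:**
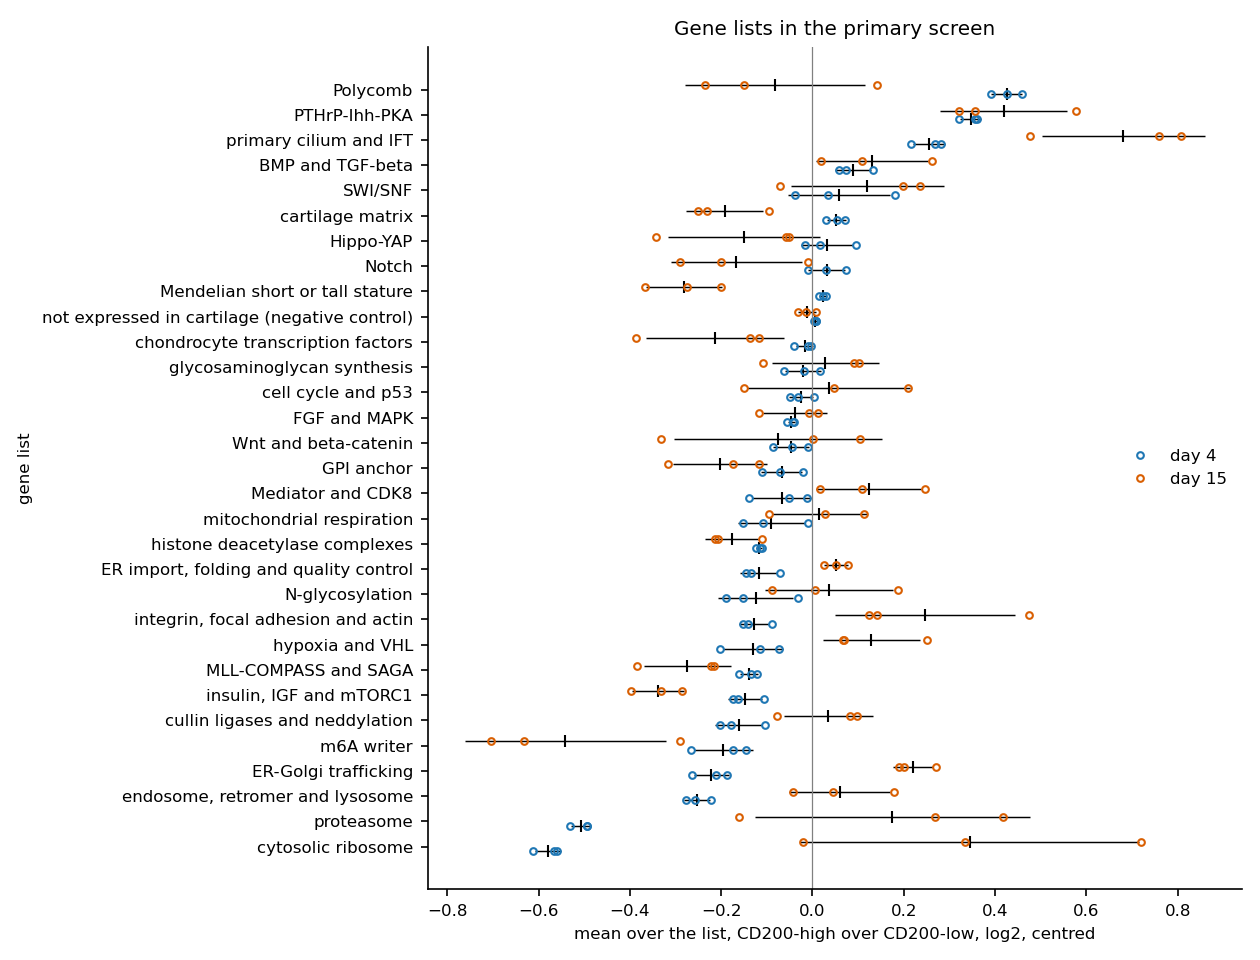
Mean centred log2 value of each gene list in the primary screen at day 4 and day 15. Open circles are the 3 replicates, the tick is their mean and the line 1 SD over replicates, and the cytosolic ribosome is the lowest list at day 4.

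The same question at day 15 of the primary screen had larger values and a wider spread. Sufu (5.60 ± 1.36) and Ptch1 (5.25 ± 0.35) were the highest. They were followed by Fkbp1a, which encodes a protein that holds BMP and TGF-beta type I receptors inactive (3.85 ± 0.57), and Smad6, an inhibitor of BMP signalling (3.08 ± 0.81). Fuz (2.91 ± 0.43) and Wdpcp (2.37 ± 0.90) act in the assembly of cilia, and Csnk2b (2.87 ± 0.75), Arrb2 (2.73 ± 0.85), Edc4 (2.64 ± 0.86) and the Notch ligand regulator Mib1 (2.63 ± 1.00) completed the 10 highest. The lowest was Prkar1a (chromosome 11, 109649023 to 109669663) at -4.71 ± 0.65 (adjusted p = 4.63e-10). Cop1 lay at -3.98 ± 1.46, Pdcd10, a partner of Ccm2, at -3.06 ± 1.01, and Tsc2 at -2.83 ± 1.47. They were followed by the translation factor gene Eif3h (-2.73 ± 1.05), Hivep1 (-2.69 ± 1.01), the Mediator subunit gene Med12 (-2.47 ± 0.86), Gnptab (-2.39 ± 0.26), Skor1 (-2.39 ± 0.43) and Neurl1a (-2.34 ± 0.87).

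At day 15 the primary cilium list was higher in 6 of 36 members and lower in 1 (adjusted over the list alone, 14 and 1), with a mean of 0.68 (camera adjusted p = 3.22e-08, and adjusted p = 0.65 with an estimated correlation). Ift172 (1.81 ± 0.12), Ift88 (1.66 ± 1.27), Kif3a (1.63 ± 0.56) and Ift57 (1.57 ± 0.22) led it. The m6A writer list was lower in 2 of 13 members and higher in 0 (adjusted over the list alone, 4 and 0), with a mean of -0.54 (camera adjusted p = 0.04, and adjusted p = 0.652 with an estimated correlation), Mettl14 at -2.05 ± 0.18 and Wtap at -1.33 ± 0.98. By the rank test of the lists this call was lost (adjusted p = 0.0925). The cytosolic ribosome was higher as a list, with a mean of 0.34 (camera adjusted p = 0.00367), but none of its 45 members was past the threshold by either adjustment. Its largest values were those of Rps24 (1.11 ± 0.24), Rps6 (1.08 ± 0.34), Rpl6 (0.94 ± 0.25) and Rpl23 (-0.79 ± 0.49), and the list mean was 0.72 and 0.33 in replicates 1 and 2 but -0.02 in replicate 3. With an estimated correlation its adjusted p = 0.672. The PTHrP-Ihh-PKA list had 3 of 22 members higher and 2 lower (adjusted over the list alone, 3 and 3, camera adjusted p = 0.091), and insulin, IGF and mTORC1 genes 1 of 36 higher and 2 lower (adjusted over the list alone, 1 and 3, camera adjusted p = 0.0876). The remaining lists had camera adjusted p values of 0.0905 or more.

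In the test at day 15, 732 of 20710 genes were past the threshold, 226 higher and 506 lower. Control guide groups passed at least as often (13 of 250, or 5.2%, against 3.54% of genes), and across guides 20 of the 732 genes also stood apart from random sets of control guides, 14 higher and 6 lower, with 0 of the 1450 receptor genes among them, of which 41 (2.83%) passed by limma. Of the genes named above, Med12, Gnptab, Skor1 and Neurl1a were not past that second test, nor were the named members of the cilium list (Ift172, Ift88, Kif3a and Ift57) and of the m6A list. A gene that missed it is not thereby shown to be unchanged. In simulation the related test against random sets of all guides recovered 37.5% of shifts of 2 at day 15. The 92% recovered by limma came from a simulation without spread between guides, so these shares do not compare the tests. The deposited values had medians of 0.87, 0.96 and 0.43 in the 3 replicates, and without centring 7254 genes were higher and 101 lower.

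The day 15 minus day 4 comparison in the primary screen asked which knockouts shifted CD200 differently at the later day. The values were higher at day 15 for Fkbp1a (by 3.46, SE 0.34), Ptch1 (by 3.40, SE 0.29), Csnk2b (by 3.19, SE 0.40), Mib1 (by 2.35, SE 0.47) and Fuz (by 2.32, SE 0.30), with adjusted p from 0.0106 to 0.0483. Prkar1a fell by 3.70 (SE 0.35, adjusted p = 0.0127). The difference was -2.73 for Eif3h (SE 0.47), -2.66 for Med12 (SE 0.42) and -2.61 each for Skor1 and Dot1l (SE 0.30 and 0.40), with adjusted p from 0.0342 to 0.0466. Guides against Dot1l were thus more abundant in CD200-high cells at day 4, while its value at day 15 was -0.70 ± 0.80 and did not pass (adjusted p = 0.289). The difference for Cd200 was 0.57 (SE 0.31, adjusted p = 0.302) and did not pass.

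By list, the difference was positive for the cytosolic ribosome (mean 0.92, 3 of 45 members past the threshold and 30 adjusted over the list alone, camera adjusted p = 1.37e-14), with Rps24 at 1.87, Rps6 at 1.57 and Rpl6 at 1.47. Rps24 and Rpl6 have no guide of their own and share guides with Rps24-ps3 and Rpl6l, so their values are uncertain at either day. It was positive for the proteasome (mean 0.68, 0 of 32 members past the threshold and 2 adjusted over the list alone, camera adjusted p = 1.33e-06), whose largest differences were those of Psmd11 (1.60), Psmd7 (1.38), Psmb7 (1.28) and Psma1 (1.15). ER-Golgi trafficking (mean 0.44, 3 of 43 members higher, camera adjusted p = 0.00102) held the coatomer genes Copb2 (1.54), Arcn1 (1.53) and Copa (1.48). The endosome list (mean 0.31, 1 of 33 higher and 1 lower, camera adjusted p = 0.00991) had Atp6v1a at 1.64 and Snx27 at -1.51. The cilium list (mean 0.43, 1 of 36 higher, camera adjusted p = 0.00286) had Ift172 at 1.67, and the integrin and actin list (mean 0.37, 1 of 33 higher, camera adjusted p = 0.00847) Actr3 at 1.38. Adjusted over the list alone, the counts higher and lower were 7 and 1 for ER-Golgi trafficking, 9 and 3 for the endosome, 4 and 1 for the cilium and 3 and 1 for integrin and actin. The Polycomb list was lower (mean -0.51, 1 of 24 members and 4 adjusted over the list alone, camera adjusted p = 0.00773), with Ezh2 at -1.65. With an estimated correlation, the adjusted p = 0.28 for the ER-Golgi, cilium and Polycomb lists and adjusted p = 0.282 for the ribosome, proteasome, endosome and integrin lists, and no list passed. The estimated correlation was 0.34 for the ribosome and 0.16 for the proteasome, far above the preset 0.01. Their p-values with the preset correlation are thus likely too small.

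The difference was past the threshold for 282 genes, 126 higher and 156 lower at day 15. The count was 0 when any of the 3 day 4 replicates was left out and 1000 to 2475 when a day 15 replicate was left out, and centring on control guides gave 352 higher and 173 lower. At both days 110 genes passed, 96 with the same sign and 14 with opposite signs, where independent lists would give 50.9 and 35.0. Across genes, which are not independent replicates, the day means correlated with r = 0.060.

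The secondary screen asked whether genes chosen on the primary screen moved CD200 with more guides per gene. Because its genes were chosen on the primary screen, their directions in the primary screen are not independent evidence. At day 4 the highest were Sufu (2.19 ± 0.19), Eed (1.85 ± 0.34), Ptch1 (1.33 ± 0.19), Ezh2 (1.29 ± 0.41), Suz12 (1.16 ± 0.25) and Urod, an enzyme of haem synthesis (1.05 ± 0.12). They were followed by Trp53, the gene of p53 (0.76 ± 0.26), Rbpj, the transcription factor of Notch signalling (0.72 ± 0.29), Gnas (0.69 ± 0.24) and Ptbp1 (0.65 ± 0.06). After Cd200, the lowest genes with guides of their own were Brd2 (-0.95 ± 0.53) and the proteasome gene Psmc4 (-0.95 ± 0.44). Gm10263, Gm13192 and Gm20568 (-1.03 ± 0.54 each) and Gm10443 (-0.98 ± 0.50) were also among the lowest. These are pseudogene entries without a guide of their own, and since they share their guides with Rps28 their values cannot be told from those of that partner.

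At day 15 of the secondary screen Sufu (5.26 ± 0.51) and Ptch1 (4.77 ± 0.61) were highest, followed by Urod (2.99 ± 1.84), Gnas (2.67 ± 0.45), Csnk2b (2.22 ± 1.08), the Rps28-sharing Gm20568, Gm13192 and Gm10263 (1.96 ± 1.16 each), the Hippo pathway effector Yap1 (1.93 ± 0.89) and Eed (1.84 ± 1.18). The lowest were Eif3h (-3.37 ± 0.88), Cop1 (-2.62 ± 0.26) and Det1, a partner of COP1 in a ubiquitin ligase (-2.47 ± 0.88). Gm6206, whose 4 guides are all shared with Cop1, lay at -2.42 ± 0.22. Prkar1a (-2.30 ± 0.60), the Mediator gene Med26 (-2.13 ± 0.40), Phf12 (-2.11 ± 0.71), Kdm1a (-1.82 ± 0.92) and Tsc2 (-1.78 ± 0.68) followed.

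**Figure D3:**
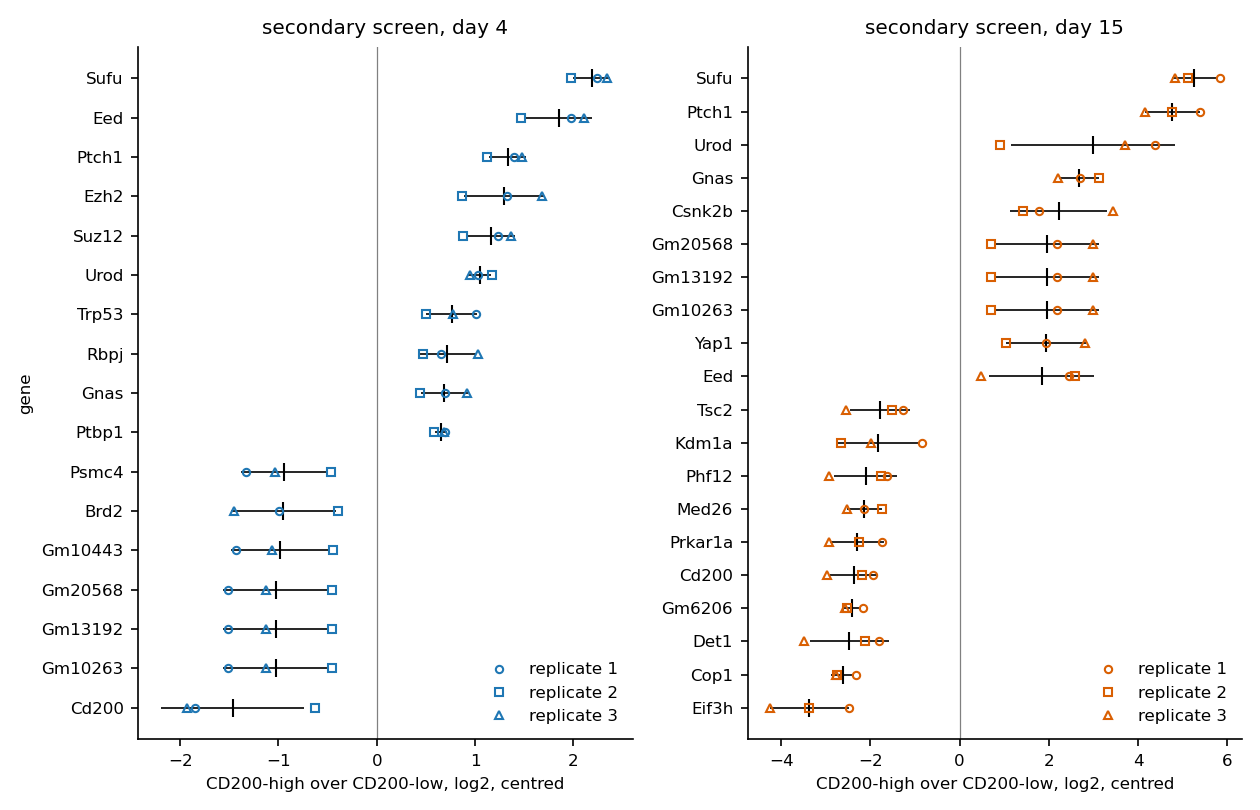
Centred log2 values of Cd200 and of the highest and lowest genes named by rule in the secondary screen at each day, up to 10 of each. Open symbols are the 3 replicates, the tick is their mean and the line 1 SD, and replicate 2 lies nearer 0 than the others for most genes at day 4.

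At secondary day 4, 160 of 238 genes were past the threshold, 38 higher and 122 lower, of which 28 had no guide of their own, and 0 of 22 control guide groups passed. The count was 0 without replicate 1 or without replicate 3 and 162 without replicate 2, whose SD over genes was 0.527 of the mean of the others, while random sets of control guides gave 210. At secondary day 15, 89 genes were past the threshold, 64 higher and 25 lower, of which 14 had no guide of their own, and random sets of control guides gave 151. Centring on the median of the selected genes instead of the control guides gave 73 higher and 88 lower at day 4 and 46 higher and 31 lower at day 15.

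Between the days of the secondary screen, Ptch1 rose by 3.44 (SE 0.32) and Sufu by 3.07 (SE 0.28), each with adjusted p = 0.00304. The Rps28-sharing Gm20568, Gm13192 and Gm10263 rose by 2.99 (SE 0.60, adjusted p = 0.011). Eif3h fell by 2.94 (SE 0.43), Cop1 fell by 1.90 (SE 0.23) and Gm6206 fell by 1.71 (SE 0.23), each with adjusted p = 0.0056. Det1 fell by 1.98 (SE 0.44, adjusted p = 0.0144) and Prkar1a fell by 1.67 (SE 0.32, adjusted p = 0.0106). The difference for Cd200 was -0.90 (SE 0.43, adjusted p = 0.167) and did not pass. The 4 measured members of the ribosome list (Rpl13, Rpl37, Rps2 and Rps3) and the 3 of the proteasome list (Psma6, Psmc4 and Psmd14) were each past the threshold at both days, lower at day 4 and higher at day 15.

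In all, 82 genes were past the threshold for the secondary difference, 69 higher and 13 lower at day 15, and 57 higher and 58 lower when centred on the median of the selected genes. At both days 85 genes passed, 35 with the same sign and 50 with opposite signs, 49 of them lower at day 4 and higher at day 15, where independent lists would give 23.0 and 36.8. Of these 49 genes, 11 had no guide of their own, and the overlap of independent lists does not allow for shared guides. Without day 4 replicate 1 the difference was past the threshold for 54 genes, and without day 15 replicate 1 for 44.

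**Figure D4:**
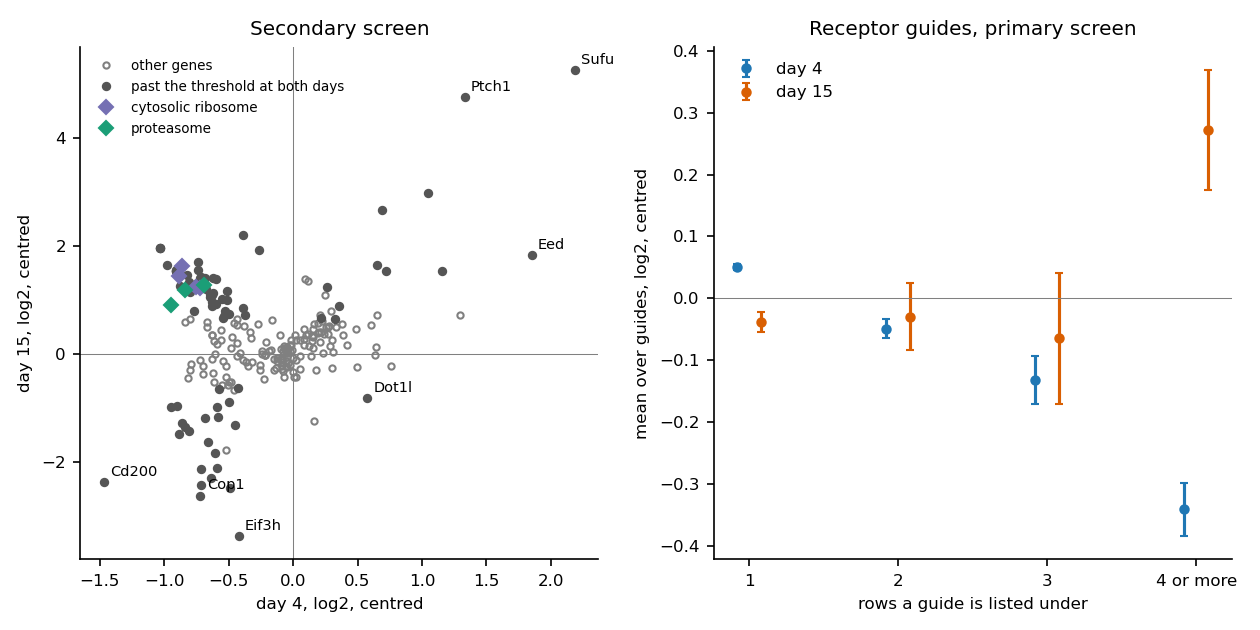
The left panel plots each gene of the secondary screen at day 4 against day 15 (centred log2), with ribosome and proteasome members as diamonds. The right panel plots the mean centred log2 value of receptor guides in the primary screen by the number of genes a guide is listed under, with bars of 1 SE over guides; at day 4 the mean is lower for guides listed under more genes.

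Both screens could be compared for 217 genes. At day 4, 125 genes were past the threshold in both with the same sign, 32 higher and 93 lower, where independent lists would give 8.96 and 46.0. With the secondary guides that are absent from the primary library, chosen after seeing the data, the count was 122. Of the 125 genes, 118 had a guide of their own in the secondary library. The overlaps and intervals given here take genes as independent, although some share guides. Of the genes past the threshold in both, 99.2% had the same sign (95% exact binomial interval 95.7% to 99.98%). The 1 exception, named after its values were seen, was Yap1, at 0.48 ± 0.33 in the primary and -0.26 ± 0.13 in the secondary screen. At day 15, 28 genes were past the threshold in both screens, 12 higher and 16 lower (independent lists would give 9.28 and 2.33), all with the same sign (95% exact binomial interval 87.7% to 100%). They included Sufu, Ptch1, Csnk2b, Prkar1a, Cop1, Eif3h and Cd200. Of the highest and lowest genes named at primary day 15, Smad6 (0.35 ± 0.34), Fuz (0.46 ± 0.11), Arrb2 (0.46 ± 0.17), Edc4 (0.55 ± 0.22), Wdpcp (0.52 ± 0.28) and Med12 (-1.24 ± 1.02) had the same sign but did not pass in the secondary screen. Hivep1, Gnptab, Skor1 and Neurl1a were not among the genes tested there. Of the 60 among the 217 genes that were past the threshold in the primary screen at day 15, 56 had the same sign in the secondary screen. Across genes, which are not independent replicates, the means of the screens correlated with r = 0.953 (rho = 0.915) at day 4 and r = 0.694 (rho = 0.549) at day 15. The day 4 count was 0 without secondary replicate 1 or without secondary replicate 3.

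**Figure D5:**
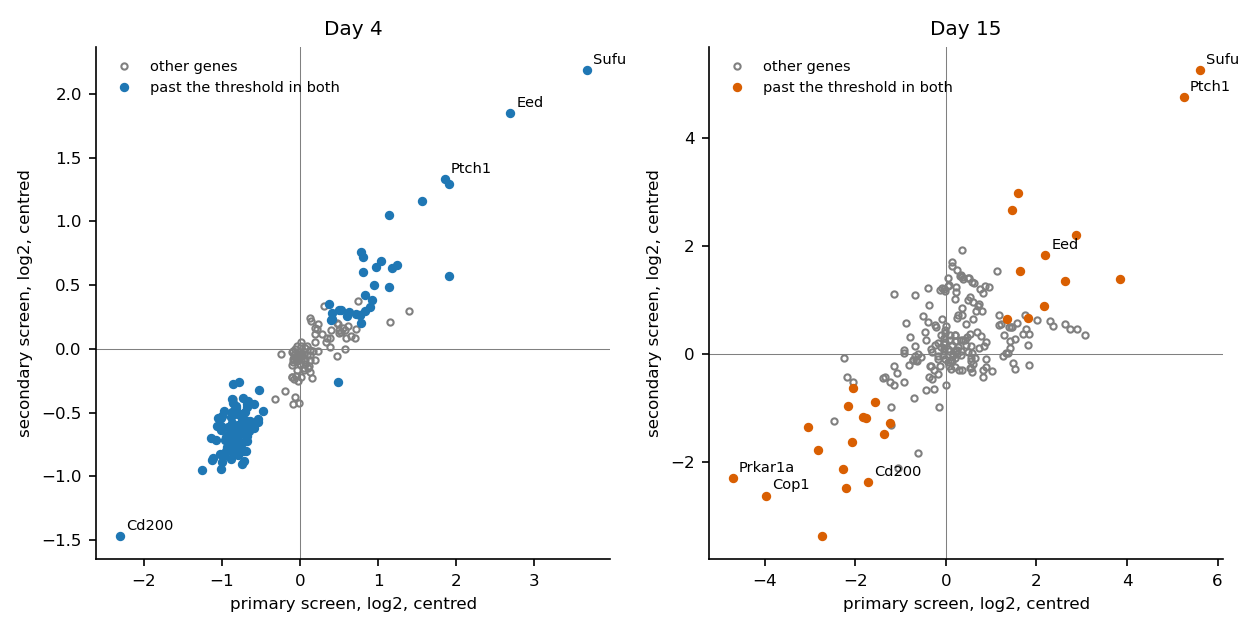
Centred log2 means of the 217 genes measured in both screens, with the primary screen on the horizontal and the secondary screen on the vertical axis, at day 4 (left) and day 15 (right). Filled points are genes past the threshold in both, of which 125 at day 4 and 28 at day 15 had the same sign.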

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

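Of the tests below, those of centring and GC content, the secondary control guides, receptor genes joined into groups, the day 15 test of ribosome guides of their own and the splits of the replicates were chosen after the results were seen. The rules of the ribosome tests (centring, own guides and guides at 0.00) were rewritten more than once after earlier forms had been run, the last time to use the change paired by replicate or, for guides at 0.00, their share, and that of the control guides once, after a form that compared counts alone.

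Values differed between day 4 and day 15 by a test of the difference itself for these genes and lists. In the primary screen these were Prkar1a (-3.70), Eif3h (-2.73), Med12 (-2.66), Skor1 (-2.61), Dot1l (-2.61), Fkbp1a (3.46), Ptch1 (3.40), Csnk2b (3.19), Mib1 (2.35) and Fuz (2.32), as day 15 minus day 4. In the secondary screen they were Eif3h (-2.94), Det1 (-1.98), Cop1 (-1.90), Gm6206 (-1.71), Prkar1a (-1.67), Ptch1 (3.44), Sufu (3.07), and Gm20568, Gm13192 and Gm10263 (2.99 each). List means differed for the cytosolic ribosome (0.92), the proteasome (0.68), ER-Golgi trafficking (0.44), the primary cilium (0.43), integrin and actin (0.37), the endosome (0.31) and Polycomb (-0.51), and none of these 7 passed with an estimated correlation (adjusted p = 0.28 to 0.282). The 10 splits of the 6 replicates of a screen are too few for a share under 0.05. The real split gave 282 genes in the primary screen, 82 in the secondary screen and 7 lists, and the highest of the other splits gave 0, 0 and 3. In each case 1 of the 10 splits, the real one, gave as many.

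Genes without a guide of their own lay low at primary day 4, where their mean minus that of genes whose guides were all their own was -0.24. Copies of ribosomal and other essential genes are argued against as the whole account by the olfactory and vomeronasal receptor genes, where the difference was -0.36. The 111 receptor genes without their own guide share guides with each other and are not independent, and when genes joined by shared guides were averaged into 21 groups it was -0.16 at day 4 (SE 0.05, permutation p = 2e-05) and -0.05 at day 15 (SE 0.10, permutation p = 0.669). At day 4 the groups had a wider spread than the single genes (SD 0.225 against 0.156). The permutation does not allow for this, so its p at day 4 may be too small. A candidate explanation that remains open, for day 4 alone, is that cutting the DNA, more so at several sites, lowers the value whatever the gene: receptor guides listed under 1, 2, 3 and at least 4 genes had means of 0.05, -0.05, -0.13 and -0.34 at day 4 but -0.04, -0.03, -0.06 and 0.27 at day 15 (guides of a gene family are not independent). Secondary guides with 1 intergenic site differed from guides with no site by -0.0833 at day 4 (SE 0.0123, permutation p = 1e-05, the smallest it can give) and by -0.06 at day 15 (SE 0.07, permutation p = 0.342). These SE and p are over guides, which share the same cultures, and do not measure the spread between replicates. By replicate the day 4 difference was -0.14, -0.04 and -0.07. In the primary screen the day 4 difference was 0.0456 (SE 0.075, 12 intergenic guides), too few guides to decide.

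Ribosome knockouts were low at day 4 in both screens and, at day 15, high in the secondary screen and as a list in the primary screen, a call that was lost with an estimated correlation (adjusted p = 0.672), while the proteasome was high at day 15 in the secondary screen alone. Centring on genes is argued against, since the primary list mean centred on control guides was -0.68 at day 4 and 0.34 at day 15, a change paired by replicate of -0.10 (SD 0.01) and -0.00453 (SD 0.07), and the secondary screen was centred on control guides. Guides at 0.00 at day 15 were 2 of 186 ribosome guides (1.08%, against 1.36% of all guides). Since 0.00 lies below the deposited replicate medians of 0.87, 0.96 and 0.43, such guides could only lower the centred mean. Their share therefore decides nothing about why the mean was positive. Guides close to lost but not at 0.00 were not tested. Shared copies are argued against at day 4 for the 15 members with at least 3 guides of their own, whose mean on those guides alone was -0.63 (SD 0.09). At day 15 that mean was 0.40 (SD 0.52), within its spread, so it decides nothing there. The change from all guides was -0.000928 (SD 0.01) at day 4 and 0.05 (SD 0.10) at day 15. Few guides of these members were left out, so a small change says little by itself. The other members were not covered, and guides could cut copies that the library does not list. The primary day 15 mean itself lay within its spread (SD 0.37), and time in culture, which the design varies, stays open and untested.

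Some groups of control guides passed the test of replicates in the primary screen. At day 4, 18 of 250 passed, all higher, and 5 of these remained when centred on control guides, where 9 passed in all, so the centre is a candidate explanation for most of them. At day 15, 13 passed and 12 of these remained. Both centres nearly coincided there, with the control groups at a median of 0.0056 and an SD of 0.61 around the gene centre. The count could therefore hardly change, and it is the small offset that argues against the centre there. Control guides correlated between day 15 replicates with a mean r of 0.337 before and 0.336 after a GC trend was removed. These values are across guides, which are not independent replicates, and argue against GC content as the source of that correlation. The groups past the threshold were not counted again without the trend. Replicates that share transduced cells could give such a correlation, which these values leave open, and no biological explanation was tested.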

How the results depend on the processing

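The fits with guides listed under 1 gene, the test against control guides and the fits without primary guides were chosen after seeing the data, and the cause of a change was not tested unless stated. At primary day 4 (2429 genes) both days in one fit gave 3, random sets of all guides 873, the deposited p 436, guides listed under 1 gene 1605, and leaving out a replicate 1277 to 2093. At primary day 15 (732) the median over guides gave 477, no minimum of guides 379, no centring 7355, both days in one fit 3832, random sets of all guides 10, of control guides 20, the deposited p 9, and leaving out a replicate 200 to 465. One fit for both days shares 1 spread between a narrow and a wide day. At secondary day 4 (160) one fit gave 1 and leaving out a replicate 0 to 162. At secondary day 15 (89) random sets of all guides gave 59 and of control guides 151. For the primary difference (282) the median over guides gave 3, scaling 1628 (1113 higher, 515 lower), robust eBayes 103, no centring 6808 (6738 higher, 70 lower), control-guide centring 525, weights per day 711, guides listed under 1 gene 69, and leaving out a replicate 0 to 2475. For the secondary difference (82) scaling gave 150 and leaving out a replicate 44 to 93. The labels do not say whether a replicate number is shared by the days. Deviations of same-numbered replicates from their day means correlated with r = 0.015, -0.012 and 0.001 in the primary screen. In the secondary screen r was -0.039, -0.414 and 0.100, and not every sample correlated best with its own number. Such deviations sum to 0 over the 3 replicates of a day, so they do not settle whether the numbers pair the samples. The replicate block gave 858, 63 and 7 for the primary genes, secondary genes and lists. For both screens (125 and 28) leaving out a replicate gave 0 to 128 at day 4, and at day 15 control guides gave 18 and the same sign alone 56. The lists past the threshold (13, 3 and 7) were 0, 0 and 0 with an estimated correlation, which rests on 2 or 4 residual degrees of freedom. Cd200 stayed negative throughout, from -1.85 to -1.51 at primary day 15 and from -1.89 to -1.24 at secondary day 4 when a replicate was left out, and lost the threshold without replicate 3 and without replicates 1 or 3. For the highest and lowest genes named by rule, under the median over guides, random sets of all guides, the replicate block and left-out replicates where each was run, 452 combinations kept side and direction, 93 lost the threshold and 0 reversed. Counts not listed stayed within 1.5 times the main count. The depth is unknown, so its limits cannot be given.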

Other observations

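The gene groups here were chosen after their values were seen, outside the rule for named genes, and the values are centred log2 means ± SD (n = 3) with limma's threshold. All 3 genes of the cerebral cavernous malformation complex, which restrains a MAP kinase cascade, were lower at both days in both screens by limma. In the primary screen Ccm2, Krit1 and Pdcd10 lay at -1.12 ± 0.27, -0.68 ± 0.10 and -0.97 ± 0.06 at day 4 and at -1.23 ± 0.48, -1.77 ± 0.24 and -3.06 ± 1.01 at day 15. In the secondary screen they lay at -0.86 ± 0.43, -0.69 ± 0.31 and -0.84 ± 0.35 at day 4 and at -1.27 ± 0.32, -1.19 ± 0.34 and -1.36 ± 0.67 at day 15. Det1 and Cop1, which act in one ubiquitin ligase, were also lower at both days in both screens, Det1 at -0.47 ± 0.17 and -2.21 ± 0.37 in the primary screen. Of the 4 other genes of this ligase in the primary screen, Dda1, Cul4a and Cul4b passed at neither day and Ddb1 was lower at day 4 (-0.47 ± 0.20) but did not pass at day 15 (mean 0.43). Across guides Ccm2, Krit1 and Det1 did not stand apart from control guides at primary day 15 (adjusted p = 0.938, 0.552 and 0.283). At secondary day 4 no gene, these included, passed when replicate 1 or replicate 3 was left out.

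Among transcription factors of chondrocytes, Sox9, Runx2 and Foxc1 were lower at both days of the primary screen, with Sox9 at -0.87 ± 0.26 and -1.57 ± 0.62, Runx2 at -0.94 ± 0.13 and -1.39 ± 1.18, and Foxc1 at -0.996 ± 0.13 and -1.36 ± 1.12. In the secondary screen Sox9 (-0.50 ± 0.22 and -0.88 ± 0.27) and Foxc1 (-0.89 ± 0.37 and -1.49 ± 0.34) were lower at both days, and Runx2 at day 4 (-0.81 ± 0.34) but not at day 15 (-0.45 ± 0.41, adjusted p = 0.185). Sox6 was higher at day 4, at 0.81 ± 0.22 in the primary and 0.61 ± 0.29 in the secondary screen, where it did not pass at day 15 (0.53 ± 0.20, adjusted p = 0.0765). At primary day 15 it was not past the threshold as higher either, since 0 of the 23 measured members of its list were. Across guides the day 15 values of Sox9, Runx2 and Foxc1 in the primary screen did not stand apart from control guides (adjusted p = 0.805, 0.869 and 0.869). Dot1l was 0.58 ± 0.17 at day 4 and -0.81 ± 0.05 at day 15 in the secondary screen, both past the threshold. Trp53 lay at 0.79 ± 0.09 at primary day 4 and did not pass at primary day 15 (mean -0.13). Of 8 genes of haem synthesis in the primary screen, Urod and Uros were higher at day 4 and Urod alone at day 15, where it did not stand apart from control guides (adjusted p = 0.478). Of 13 genes of the translation factor eIF3, Eif3h alone was lower at primary day 15, while 5 others were lower at primary day 4. At day 4 Eif3h lay at -0.009 ± 0.07 in the primary screen but was lower in the secondary screen (-0.42 ± 0.21, adjusted p = 0.0374).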
